A study of Homo sapiens with 48 samples.

How the data were processed

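RNA was measured in 48 libraries from HEK293-derived Flp-In 293 T-REx cells. The labels place them in 16 groups of 3, made of 8 stable lines crossed with a non-targeting siRNA (siNT) or an siRNA against UPF1 (siUPF1). Per the labels' protocols, 300000 cells were seeded and transfected with 40 nM siRNA, harvested after 72 h, and 500 ng of total RNA was depleted of ribosomal RNA before paired-end sequencing. The series' design text calls the triplicates biological replicates, and the group and replicate number of each library were taken from its label.

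The deposited table held expected counts per gene for 57820 genes, not normalised, with 1 column per library. Reads had been trimmed with cutadapt, aligned with STAR and counted with RSEM, with hg19 as the genome build and DESeq2 among the tools, per the submitters' processing notes. Versions, the annotation release and the strand setting of the counting were not given in the sources used here. Reads of overlapping, antisense or near-identical genes are therefore uncertain, and the table gives gene names without coordinates. The reference annotation at hand was of GRCh38, so no coordinates were printed, and it served only for gene types, overlaps, 3′ UTR sequences, transcript lengths and GC content. Reads of the CLIP-UPF1 transgene and of the endogenous gene were counted together under UPF1 in the deposited expected counts.

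Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 16 groups, which left 19129 genes with 99.94% or more of each library's counts. Totals ran from 21.3 to 47.1 M per library, and TMM normalisation factors from 0.974 to 1.04. A quasi-likelihood model was fitted to all 48 libraries with 1 term per group, so that every comparison shared the estimate of the spread. The 28 comparisons were 8 knockdown responses (siUPF1 against siNT in a line), 7 differences of a response from that of the line with the tag alone, 6 differences from that of the wild-type line, and 7 comparisons of siNT libraries between lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Levels are CPM from edgeR, counts scaled to the normalised library total, and log2 fold changes carry the standard error (SE) of the model.

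The design, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. UPF1 came first. In each knockdown response, genes were named by the largest fold change among called genes with a mean of at least 5 CPM and every siUPF1 library on the same side of every siNT library, 15 higher and 8 lower in CLIP and 4 higher and 3 lower in each other line. Chance alone gives such a separation in 10% of genes that do not differ. In differences of responses and between siNT libraries the 3 highest and 3 lowest were taken, the separation being required for the latter only. Unnamed or overlapping loci and pseudogenes were skipped, RP9P excepted. The first 4 members, by size of the change in CLIP, of the lists of NMD factors, NMD targets, snoRNA hosts and ATF4 targets were added as examples, of which 1 is not reported here. The value of a gene named in more than 1 comparison is not printed for each. Genes named outside this rule are said to be so.

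The lists covered NMD factors other than UPF1, commonly used NMD targets, non-coding hosts of small nucleolar RNAs (snoRNA hosts), splicing factors with poison exons, ATF4 targets, endoplasmic reticulum chaperones and unfolded protein response genes, p53 targets, interferon-stimulated genes, proliferation genes, exon junction and general decay factors, cholesterol synthesis, reference genes, histones, cytoplasmic ribosomal proteins, mitochondrially encoded genes, and markers of other cell types. Each list with at least 5 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated per list and with fry. Called members were counted over all genes and with p adjusted over the list alone. The markers of other cell types had 3 tested members and were not tested as a list. Histone, ribosomal protein and mitochondrial genes have near-identical copies, and their counts are uncertain.

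The NMD target score of a library was the mean log2 CPM (prior count 2) of the 35 tested genes of the NMD target and snoRNA host lists. Differences between siUPF1 and siNT were tested by exact two-sided permutation of 3 against 3 libraries, which cannot give a p under 0.1. Differences between lines were tested by exact two-sided permutation of the line labels within each siRNA, with 400 arrangements, a smallest p of 0.005 and Benjamini-Hochberg adjustment over 13 differences. That smallest p is out of reach where the lines already differ with siNT in the direction of their difference with siUPF1.

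Replicates were compared before they were averaged. Over the 48 pairs within groups, chi-square per degree of freedom of the counts ran from 3.9 to 139 and Pearson correlations across genes from 0.969 to 0.993, so no pair matched within sampling noise. Whether replicate numbers pair siNT with siUPF1 libraries was checked from the correlation of their deviations from the group means. All 3 correlations were over 0.1 in K498A (0.157 to 0.283) and GA-KH (0.122 to 0.275) and not in the other 6 lines. Values with the replicate as a block are therefore given beside results of K498A and GA-KH where a count moved by over 1.5 times. The same number gave the highest correlation for all 3 libraries also in DE636AA, R843C and A546H. It did so for 2 of 3 in CLIP and WT and for 1 of 3 in E797R. Pairing in these lines is thus not excluded, and the main model and the score permutations hold no replicate term.

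The tests were checked on simulated counts with known changes. For the knockdown response of CLIP, 68.7% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes were recovered among 18839 genes, with 9 false calls. For the difference between WT and CLIP the shares were 32.8%, 85.1% and 97%, with 7 false calls. The simulation changed 67, 67 and 66 genes at these folds and left the others equal in all groups. Each gene had 1 spread for all libraries. With no library set apart, GC trend or replicate effect in it, these shares need not carry over to the real comparisons.

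Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit to the comparison's own libraries, the replicate number as a block, each library left out in turn, and for scores also a prior count of 0.5, the median over members and genes raised at least 2-fold in CLIP. Chosen after the data were seen were the gene lists and the counts of shared genes without CLIP siUPF1 replicate 2, gene sets chosen on other replicate numbers, and removal of GC and length trends by offsets.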

Results

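The libraries came from HEK293-derived Flp-In 293 T-REx cells, in which a transgene is placed at a fixed genomic site. The study asked how regulation of the UPF1 ATPase relates to the efficiency of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts with premature stop codons and many normal ones, and for which UPF1 is the central helicase. The line CLIP expressed the CLIP tag alone and the line WT expressed CLIP-tagged wild-type UPF1. The other 6 lines expressed CLIP-UPF1 with the changes K498A or DE636AA, which alter the ATP-binding and ATP-hydrolysis motifs of the helicase, or R843C, A546H, GA-KH or E797R. Each line had 3 siNT and 3 siUPF1 libraries. Library totals ran from 21.3 to 47.1 M expected counts (median 32.3 M), and 23288 to 26357 genes had a count. Group means ran from 28.6 ± 2.01 M (SD, n = 3) in R843C siUPF1 to 39.1 ± 7.46 M in K498A siUPF1. The first principal component of the 2000 most variable genes held 33.6% of the variance, with every siUPF1 library at 14.1 or above and every siNT library at -17 or below. CLIP siUPF1 replicate 2 stood apart from its group, with 36.8 CPM of UPF1 against 18.2 and 17.7 in replicates 1 and 3, and 0.631% of counts from mitochondrially encoded genes against 2.32% and 2.13%.

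UPF1 (ENSG00000005007.8) was measured first, as the target of the siRNA. In CLIP its level fell from 108 ± 4.14 CPM (SD, n = 3) with siNT to 24.2 ± 10.9 CPM with siUPF1. This left 22.4% (log2 fold change -2.17, SE 0.17, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.83e-13). In the 7 lines with CLIP-UPF1, siNT levels were 38.5 to 52 times that of CLIP. They were 5290 ± 315 CPM in WT, 5420 ± 545 in K498A, 5610 ± 673 in DE636AA, 4170 ± 55.4 in R843C, 4400 ± 540 in A546H, 4530 ± 521 in GA-KH and 5010 ± 515 in E797R. With siUPF1 they were 4840 ± 877, 5960 ± 472, 7220 ± 955, 3960 ± 297, 4350 ± 441, 4100 ± 370 and 5060 ± 946 CPM in the same order, and none of the 7 changes was called by edgeR (adjusted p from 0.0786 to 0.958). The change in DE636AA, 0.36 (SE 0.16), was called in the fit to its own libraries (0.38), with the replicate block (0.36) and with no filter on low counts (0.39). These levels are of transcripts, and loss of the endogenous part cannot be seen beneath the transgene.

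**Figure D1:**
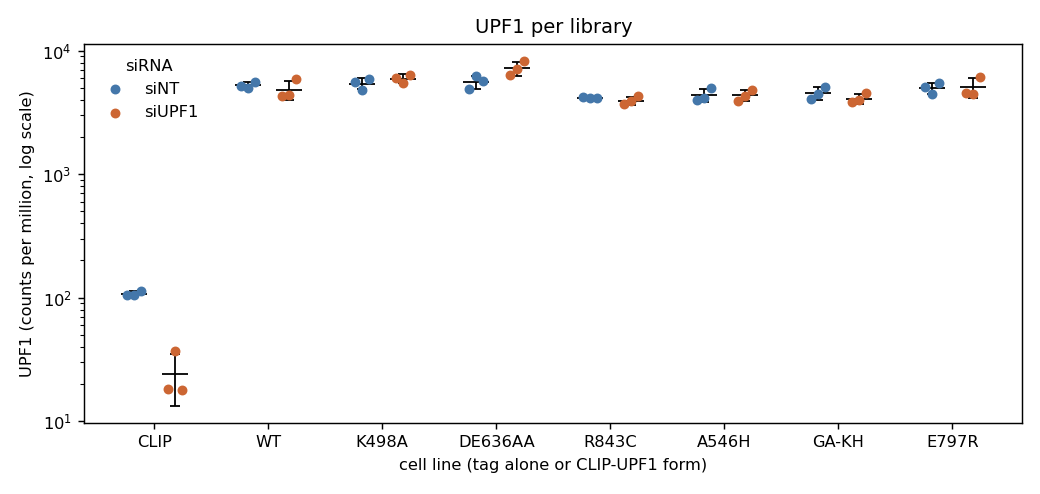
UPF1 in CPM on a log axis, for each line and siRNA; points are libraries, and bars give the mean and SD of 3. CLIP falls from 108 to 24.2 CPM, and the lines with CLIP-UPF1 stay at 3960 CPM or above in the group means.

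Knockdown in cells with the tag alone raised known NMD targets together with genes of the NMD machinery. All 15 NMD targets were called higher over all genes and 15 when adjusted over the list alone, with a median log2 fold change of 1.00 (camera adjusted p = 1.58e-09 by Benjamini-Hochberg, 0.00692 with an estimated correlation). Among them BAG1, a co-chaperone, rose by 2.30 (SE 0.15), from 47.5 ± 1.9 to 235 ± 64 CPM (SD, n = 3). RP9P, a transcribed pseudogene that shares sequence with its parent gene, rose by 2.28 (0.15), GABARAPL1, an autophagy gene, by 1.38 (0.11) and ERN1, a sensor of unfolded proteins, by 1.13 (0.13). Of 9 NMD factors 8 rose, 8 adjusted over the list alone, with a median of 0.77 (adjusted p = 9.7e-07, 0.000777 with an estimated correlation). Among them were SMG1 at 1.52 (0.08), SMG5 at 0.96 (0.10) and SMG9 at 0.83 (0.08). SMG1 has pseudogene copies, so its value is uncertain. Of 20 snoRNA hosts 16 rose and 2 fell, the same numbers adjusted over the list alone, with a median of 0.98 (adjusted p = 1.87e-07, 0.086 with an estimated correlation). C6orf48 rose by 2.03 (0.12), SNHG7 by 1.67 (0.12), SNHG8 by 1.46 (0.14) and EPB41L4A-AS1, whose antisense position makes its count uncertain, by 1.44 (0.08). The NMD target list holds ATF4 itself and other genes of stress responses, among them DDIT3 and ERN1, and ATF4 targets rose as well. Levels of RNA cannot tell slower decay from more transcription, so neither this list nor the NMD target score measures decay alone in any line.

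Stress and growth genes moved as well. Of 24 ATF4 targets, the genes of the integrated stress response, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.000102 by Benjamini-Hochberg, 0.261 with an estimated correlation). SESN2 rose by 1.96 (SE 0.13), JDP2 by 1.92 (0.21), STC2 by 1.85 (0.14) and the amino acid transporter SLC7A5 by 1.72 (0.16). Of 86 ribosomal protein genes 50 fell and 3 rose (51 and 3 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 2.67e-06, 0.418 with an estimated correlation). Of 16 proliferation genes 11 fell and 3 rose, the same adjusted over the list alone, with a median of -0.34 (adjusted p = 0.0298, 0.261 with an estimated correlation). The falls in the last 2 groups were smaller without CLIP siUPF1 replicate 2, whose change from siNT correlated with GC content across 13972 genes at a Spearman coefficient of 0.64, against 0.06 and 0.21 for replicates 1 and 3. Without that library 32 ribosomal protein genes fell and 5 rose (median -0.18, camera adjusted p = 0.00033), and 8 proliferation genes fell and 0 rose (median -0.22, camera adjusted p = 0.0154). In that fit 13 NMD targets (median 0.89), 8 NMD factors (0.72), 17 snoRNA hosts (1.02) and 15 ATF4 targets (0.48) rose.

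The remaining lists in CLIP moved less or in both directions. Endoplasmic reticulum genes had 6 of 15 higher (6 adjusted over the list alone, median 0.23, camera adjusted p = 0.0298 by Benjamini-Hochberg, 0.261 with an estimated correlation). Splicing factors had 3 of 23 higher and 10 lower (3 and 11 adjusted over the list alone, median -0.15), interferon-stimulated genes 1 of 12 and 5 (2 and 6, -0.28), cholesterol synthesis genes 5 of 15 and 8 (5 and 8, -0.31), p53 targets 6 of 14 and 3 (6 and 3, 0.13) and reference genes 3 of 12 and 3 (3 and 3, -0.11). Their camera adjusted p were 0.098, 0.0855, 0.0855, 0.858 and 0.514 by Benjamini-Hochberg. Exon junction and decay factors had 4 of 20 higher and 5 lower (3 and 5 adjusted over the list alone), with a median of 0.09 and a mean of -0.05. Histones had 6 of 59 and 7 (5 and 5), with a median of -0.03 and a mean of 0.14, and mitochondrially encoded genes 1 of 16 and 1 (0 and 0), with a median of -0.22 and a mean of 0.08. Median and mean differed in sign in these 3 lists (camera adjusted p = 0.858, 0.995 and 0.289 by Benjamini-Hochberg). Without CLIP siUPF1 replicate 2 the medians were -0.09 for cholesterol synthesis genes (3 higher, 7 lower), -0.06 for splicing factors (5 and 7), -0.23 for interferon-stimulated genes (1 and 4), 0.16 for p53 targets (4 and 4) and 0.18 for endoplasmic reticulum genes (6 and 0). They were 0.05 for exon junction and decay factors (7 and 2), -0.02 for histones (6 and 5), and changed sign for reference genes (0.04, 2 and 2) and mitochondrially encoded genes (0.14, 1 and 0). Of the 12 markers of other cell types, COL1A1, COL3A1 and EPCAM had counts enough to be tested.

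In all, 9066 of 19129 genes were called in CLIP, 4798 higher and 4268 lower, of which 1063 and 1050 changed at least 2-fold. The largest rises were of DHRS2, a short-chain dehydrogenase (log2 fold change 2.92, SE 0.25), the neuronal immediate early gene ARC (2.78, 0.30), the kinase WNK4 (2.78, 0.21) and DOK3 (2.56, 0.22). TSC22D3, a glucocorticoid-induced regulator, went from 157 ± 22 to 911 ± 188 CPM (2.54, 0.18). PAQR6, the neurotrophin receptor NGFR, TXNIP, JOSD2, ZNF185, LINC01002, the transporter SLC44A2 and the channel TRPM4 rose by 2.11 to 2.53. The largest falls were of PRDX3, a mitochondrial peroxidase, from 118 to 10.8 CPM (-3.42, SE 0.24), HRSP12 (-3.20, 0.27), and the fatty acid desaturase FADS2 (-3.14, 0.15). They were followed by the kinase MAP2K6 (-2.85, 0.20), KRCC1 (-2.61, 0.15), the lysyl oxidase LOX (-2.53, 0.18), the homeobox gene MSX1 (-2.47, 0.19) and PGM2L1 (-2.41, 0.21). Without CLIP siUPF1 replicate 2, 7872 genes were called, 6798 of them shared in direction, and a fit to the 6 CLIP libraries alone called 3741.

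In WT, which tests how far wild-type CLIP-UPF1 replaces the depleted protein, the NMD groups did not move as groups, while many other genes did. Of the 15 NMD targets 1 rose and 1 fell over all genes and adjusted over the list alone (median -0.04, camera adjusted p = 0.658 by Benjamini-Hochberg). BAG1 rose by 1.00 (SE 0.14), and RP9P (0.01, 0.15), GABARAPL1 (0.02, 0.11) and ERN1 (0.02, 0.13) were not called. Of 9 NMD factors 1 rose and 2 fell (1 and 4 adjusted over the list alone, median -0.13), and of 20 snoRNA hosts 4 rose (4 adjusted over the list alone, median 0.06). Endoplasmic reticulum genes held 8 higher of 15 (10 adjusted over the list alone, median 0.31, adjusted p = 0.00458, 0.248 with an estimated correlation). Cholesterol synthesis genes had 5 higher and 1 lower of 15 (6 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.0338, 0.248 with an estimated correlation). Histones had 11 higher of 59 (11 adjusted over the list alone, median 0.12, camera adjusted p = 0.0428, 0.873 with an estimated correlation). The test called 5211 genes, 2670 higher and 2541 lower. ENPP5 (2.09, SE 0.35), JOSD2 (1.82, 0.19), RAI2 (1.81, 0.14) and SRPR, a subunit of the signal recognition particle receptor (1.75, 0.13, from 46.5 to 156 CPM), rose most. PRDX3 (-2.82, 0.23), the transcription factor ETV5 (-2.44, 0.23) and MSX1 (-2.42, 0.19) fell most.

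The lines with changes in the ATPase motifs kept part of the rise of the NMD targets. In K498A 8 of 15 rose (9 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 1.88e-05 by Benjamini-Hochberg, 0.075 with an estimated correlation). In DE636AA 11 rose (11 adjusted over the list alone), with a median of 0.47 (adjusted p = 9.16e-06, 0.0605 with an estimated correlation). GABARAPL1 rose by 0.88 (SE 0.11) and 0.78 (0.11), RP9P by 0.98 (0.14) and 0.61 (0.14), and SMG1 by 0.67 (0.08) and 0.56 (0.08) in K498A and DE636AA. Of 9 NMD factors 4 were higher in each line (4 adjusted over the list alone in each), with medians of 0.10 and 0.08. Their camera adjusted p were 0.00426 and 0.0176 by Benjamini-Hochberg, and 0.0616 and 0.0806 with an estimated correlation. Of 20 snoRNA hosts 8 rose and 2 fell in K498A (9 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.0435, 0.744 with an estimated correlation). In DE636AA 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.0604). Cholesterol synthesis genes had 7 of 15 lower and 1 higher in K498A (7 and 1 adjusted over the list alone, median -0.29, adjusted p = 0.0151, 0.14 with an estimated correlation). In DE636AA 8 were lower and 1 higher (9 and 1 adjusted over the list alone, median -0.35, adjusted p = 0.00299, 0.0605 with an estimated correlation). K498A had 6247 genes called (3094 higher, 3153 lower), with ARC (2.69, SE 0.29), DHRS2 (2.18, 0.25), the lipolysis regulator G0S2 (2.11, 0.18) and PAQR6 (2.00, 0.20) rising most. The protease HTRA1 (-2.84, 0.19), FADS2 (-2.83, 0.14) and PRDX3 (-2.70, 0.23) fell most. DE636AA had 6559 (3195 higher, 3364 lower), led by ARC (2.94, 0.29), IGFN1 (2.79, 0.28), DHRS2 (2.44, 0.25) and G0S2 (2.30, 0.18), and by FADS2 (-3.05, 0.15), HTRA1 (-2.85, 0.20) and STMN3 (-2.70, 0.36).

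R843C came nearest to the tag alone in the medians of NMD factors and snoRNA hosts, though not in that of NMD targets. Of these 10 of 15 rose (10 adjusted over the list alone, median 0.45, camera adjusted p = 8.55e-05 by Benjamini-Hochberg, 0.114 with an estimated correlation). Of the NMD factors 7 of 9 rose (7 adjusted over the list alone, median 0.35, adjusted p = 4.75e-05, 0.00568 with an estimated correlation). Of the snoRNA hosts 14 of 20 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.59, adjusted p = 8.4e-08, 0.0982 with an estimated correlation). EPB41L4A-AS1 rose by 1.72 (SE 0.08), C6orf48 by 1.31 (0.11), GABARAPL1 by 1.21 (0.11), RP9P by 1.19 (0.14), SMG5 by 0.94 (0.10) and SMG1 by 0.93 (0.08). The line had 6213 genes called (3389 higher, 2824 lower), with DHRS2 (2.31, 0.24), PAQR6 (2.30, 0.19), JOSD2 (1.75, 0.19) and ZNF185 (1.74, 0.17) highest and PRDX3 (-3.15, 0.24), FADS2 (-2.87, 0.15) and HRSP12 (-2.74, 0.26) lowest.

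A546H moved less in the NMD targets, from a higher level with siNT. Its NMD target score was 5.32 ± 0.06 with siNT and 5.53 ± 0.06 with siUPF1 (SD, n = 3). In K498A the score was 5.13 ± 0.04 and 5.47 ± 0.04, and in DE636AA 5.16 ± 0.07 and 5.50 ± 0.08. Of the NMD targets 5 rose and 1 fell, the same adjusted over the list alone (median 0.17, camera adjusted p = 0.123 by Benjamini-Hochberg). Of the NMD factors 6 rose and 1 fell, the same adjusted over the list alone (median 0.34, adjusted p = 0.0446, 0.381 with an estimated correlation). GABARAPL1 rose by 0.86 (SE 0.11) and RP9P by 0.69 (0.14), and ERN1 was at -0.03 (0.14). Of 86 ribosomal protein genes 47 fell and 1 rose (57 and 1 adjusted over the list alone, median -0.28, adjusted p = 4.32e-10, 0.381 with an estimated correlation). Of 59 histone genes 18 fell and 2 rose (19 and 3 adjusted over the list alone, median -0.32, adjusted p = 0.0137, 0.537 with an estimated correlation). The test called 6153 genes (3288 higher, 2865 lower), led by PAQR6 (2.41, 0.20), DHRS2 (1.98, 0.25), LMLN (1.97, 0.12) and DOK3 (1.95, 0.21), and by PRDX3 (-3.06, 0.24), MSX1 (-2.91, 0.20) and HRSP12 (-2.87, 0.26).

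GA-KH and E797R had medians near those of WT in NMD targets and snoRNA hosts. Of the NMD targets 2 rose and 1 fell in each (1 and 1 adjusted over the list alone in GA-KH, 2 and 1 in E797R), with medians of -0.12 and 0.02 (camera adjusted p = 0.825 and 0.871 by Benjamini-Hochberg). Of the snoRNA hosts 3 rose and 2 fell in GA-KH (2 and 2 adjusted over the list alone, median -0.01). In E797R 4 rose and 1 fell (4 and 1, median -0.07). BAG1 rose by 0.78 (SE 0.14) in GA-KH and 0.94 (0.14) in E797R, while RP9P was at 0.33 (0.15) and 0.30 (0.15) and not called. The counts were 5412 genes (2773 higher, 2639 lower) and 5649 (3060 higher, 2589 lower). ENPP5 rose by 2.32 (0.35) in GA-KH and 2.05 (0.34) in E797R, PAQR6 by 2.30 (0.19) and 2.36 (0.19), and STMND1 by 1.82 (0.15) and 1.96 (0.15), with JOSD2 (1.83, 0.19) added in GA-KH and DHRS2 (1.93, 0.25) in E797R. The transcription factor ETV4 changed by -2.94 (0.34) and -2.93 (0.34) and PRDX3 by -2.93 (0.23) and -2.98 (0.23), followed by MSX1 (-2.87, 0.19) in GA-KH and HRSP12 (-2.70, 0.26) in E797R.

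Lists outside the NMD groups moved in several lines. Proliferation genes had, of 16, 6 lower and 1 higher in K498A (8 and 1 adjusted over the list alone, median -0.23), 7 and 1 in DE636AA (7 and 1, -0.19) and 6 and 0 in R843C (7 and 1, -0.20). The camera adjusted p were 0.00446, 0.00963 and 0.0176, and 0.14, 0.15 and 0.197 with an estimated correlation. Of 24 ATF4 targets 12 rose and 2 fell in DE636AA (12 and 2, median 0.33, camera adjusted p = 0.00626, 0.633 with an estimated correlation). Endoplasmic reticulum genes were higher, beyond CLIP and WT, in DE636AA (9 of 15, 10 adjusted over the list alone, median 0.31), E797R (9, 10, 0.36), K498A (7, 7, 0.19) and GA-KH (6, 7, 0.26). The camera adjusted p were 0.000123, 0.00025, 0.00472 and 0.0312 by Benjamini-Hochberg, and 0.0605, 0.176, 0.166 and 0.735 with an estimated correlation. In R843C and A546H 5 of 15 were higher (5 adjusted over the list alone in each, medians 0.16 and 0.13, adjusted p = 0.188 and 0.144). Ribosomal protein genes had, of 86, 30 lower and 2 higher in R843C (30 and 2 adjusted over the list alone, median -0.21, adjusted p = 6.58e-06). They had 15 and 1 in E797R (14 and 1, -0.13, 0.00102), 14 and 2 in K498A (10 and 2, -0.14, 0.0102) and 14 and 1 in GA-KH (12 and 1, -0.11, 0.0127), and no line passed with an estimated correlation (0.381 or above). Cholesterol synthesis genes had 7 lower and 2 higher in R843C (7 and 2 adjusted over the list alone, median -0.21, adjusted p = 0.0382) and 4 higher in E797R (4, 0.19, 0.0132). Neither passed by camera with an estimated correlation (adjusted p = 0.197 and 0.176).

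A common response ran through all lines. It held 1099 genes called higher and 1003 called lower in every one of the 8, PRDX3 among the latter. Of the 4798 genes called higher in CLIP, R843C shared 2965 (61.8%), A546H 2534 (52.8%), K498A 2250 (46.9%), DE636AA 2175 (45.3%), E797R 2140 (44.6%), WT 1999 (41.7%) and GA-KH 1957 (40.8%), where independent lists of the same lengths would share 670 to 850. Knockdown responses of different lines share no libraries. Spearman correlations with the CLIP response across genes, which are not independent replicates, ran from 0.558 in GA-KH to 0.765 in R843C.

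**Figure D2:**
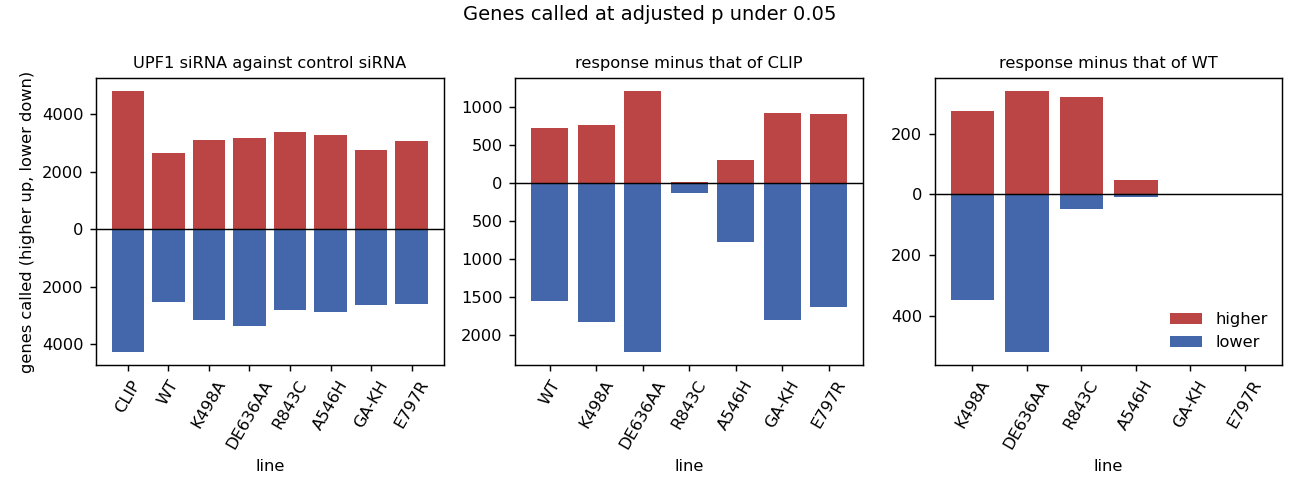
Number of genes called at an adjusted p under 0.05 (edgeR), higher above the zero line and lower below it, in the knockdown response of each line and in its difference from CLIP and from WT; each panel has its own axis. The knockdown responses run from 5211 genes in WT to 9066 in CLIP in the fit to all libraries, and the differences from WT reach 0 in GA-KH and E797R. Fits to each line's own libraries gave another order, with 3741 in CLIP, 4272 in WT and 8765 in R843C.

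The differences of responses compare each line with CLIP-UPF1 with the line that has the tag alone. With 1 line per form, the form of UPF1 and the line cannot be separated. In WT minus CLIP, 8 of 9 NMD factors were lower (8 adjusted over the list alone, median -0.82, camera adjusted p = 8.17e-14 by Benjamini-Hochberg, 1.12e-06 with an estimated correlation). Of the 15 NMD targets 14 were lower (15 adjusted over the list alone, median -1.10, adjusted p = 8.14e-19, 8.92e-05 with an estimated correlation), and of the 20 snoRNA hosts 15 were lower and 1 higher (15 and 2, median -0.92, adjusted p = 1.43e-11, 0.0132 with an estimated correlation). Of the ATF4 targets 10 of 24 were lower (15 adjusted over the list alone, median -0.55, adjusted p = 1.47e-08, 0.0918 with an estimated correlation). Of the cholesterol synthesis genes 8 of 15 were higher (10 adjusted over the list alone, median 0.43, adjusted p = 2.25e-07, 0.000845 with an estimated correlation). RP9P was at -2.27 (SE 0.21), NUPR1, a stress-induced nuclear protein, at -1.92 (0.41), LINC01002 at -1.88 (0.27), SMG1 at -1.51 (0.11) and BAG1 at -1.30 (0.20). MAP2K6 (2.53, 0.26), METTL7A (1.73, 0.18) and UPF1 itself (2.04, 0.23) stood above. GA-KH and E797R gave medians for NMD targets of -1.11 (14 lower, 15 adjusted over the list alone) and -1.06 (13 lower, 14 adjusted over the list alone), with estimated-correlation adjusted p = 0.000154 and 0.000212 by camera. A546H gave -0.79 (12 lower, 14 adjusted over the list alone, 0.000264 with an estimated correlation).

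K498A, DE636AA and R843C differed less from CLIP in the NMD targets. Medians were -0.50 (8 lower, 9 adjusted over the list alone) in K498A, -0.54 (8 lower, 9) in DE636AA and -0.46 (3 lower, 12) in R843C. The camera adjusted p were 1.12e-05, 8.92e-05 and 5.04e-13 by Benjamini-Hochberg and 0.0525, 0.115 and 0.00116 with an estimated correlation. For snoRNA hosts the medians were -0.61 (13 lower, 16 lower and 1 higher adjusted over the list alone), -0.71 (15 lower, 16) and -0.17 (4 lower, 7 lower and 1 higher). The camera adjusted p were 7.05e-09, 6.9e-08 and 0.0257, and 0.0525, 0.0945 and 0.612 with an estimated correlation. Without CLIP siUPF1 replicate 2 the median in R843C was -0.30 (4 lower, camera adjusted p = 6.03e-07). C6orf48 was at -1.71 (SE 0.16) in K498A and -1.82 (0.16) in DE636AA, NT5M at -1.90 (0.37) and -1.99 (0.37), and WDR83 at -1.49 (0.18) in K498A. The smooth muscle actin gene ACTA2 was at 1.44 (0.22) and 1.83 (0.22). In R843C, TSC22D3 was at -1.46 (0.24), SNHG8 at -1.15 (0.20) and TRIB3 at -1.23 (0.27), and MAP2K6 at 1.65 (0.27) and TXLNB at 0.81 (0.14). The calls of these 5 genes were lost in a fit to the 12 libraries alone, and that of TRIB3 also without R843C siUPF1 replicate 1 (adjusted p = 0.0548, edgeR).

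Counts of genes that differed from CLIP were 2267 in WT (722 higher, 1545 lower), 2599 in K498A (769, 1830), 3430 in DE636AA (1208, 2222), 144 in R843C (21, 123), 1077 in A546H (307, 770), 2734 in GA-KH (928, 1806) and 2539 in E797R (909, 1630). Among the 3 genes named on each side, CNTN1 was higher in A546H (1.30, SE 0.16) and GA-KH (1.60, 0.15) and TMEM255A in E797R (1.62, 0.21), and SNHG7 was lower in A546H (-1.70, 0.17) and ZFAND2A in E797R (-2.20, 0.18). LINC01002 was lower in GA-KH (-2.08, 0.27) and E797R (-1.91, 0.27). Without CLIP siUPF1 replicate 2 the counts were 1978, 2064, 2722, 183, 820, 1970 and 2122, of which 1507, 1537, 2134, 102, 597, 1609 and 1635 genes were shared in direction. A fit to the 12 libraries of each comparison called 522, 365, 496, 0, 105, 647 and 684. Without CLIP siUPF1 replicate 1 the counts were 3744, 4438, 5162, 570, 3300, 4967 and 4263. With the replicate as a block they were 4136 in K498A and 4556 in GA-KH. Without CLIP siUPF1 replicate 3 the count was 3468 in WT, 249 in R843C, 2145 in A546H and 4240 in GA-KH. In A546H it was 650 without CLIP siNT replicate 2, 596 without its own siNT replicate 3 and 635 without its own siUPF1 replicate 1. In R843C it was 94 without CLIP siNT replicate 3, 87 without its own siNT replicate 2 and 85 without its own siUPF1 replicate 1. It was 1593 in K498A and 1767 in GA-KH without the siNT replicate 3 of each line.

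Against WT, NMD targets and factors were higher in 4 lines. NMD targets had medians of 0.50 in K498A (5 of 15 higher, 11 adjusted over the list alone), 0.49 in DE636AA (6 higher, 14), 0.42 in R843C (4 higher, 11) and 0.18 in A546H (1 higher, 2). The camera adjusted p were 7.52e-13, 1.84e-12, 8.44e-13 and 0.000231 by Benjamini-Hochberg and 0.000845, 0.00118, 0.00116 and 0.0978 with an estimated correlation. NMD factors had 5 of 9 higher in K498A (6 higher and 1 lower adjusted over the list alone, median 0.40), 4 higher and 1 lower in DE636AA (5 and 1, 0.35), 5 higher in R843C (7, 0.53) and 3 higher in A546H (5, 0.39). By camera with an estimated correlation the adjusted p were 6.69e-05, 0.00118, 5.16e-07 and 8.48e-05 in that order. SMG1 was at 0.65 (SE 0.11), 0.55 (0.11), 0.92 (0.11) and 0.58 (0.11) in that order, and GABARAPL1 at 0.86 (0.15), 0.76 (0.15), 1.18 (0.15) and 0.84 (0.15), all called. In R843C, 9 of 20 snoRNA hosts were higher (10 adjusted over the list alone, median 0.55, adjusted p = 5.55e-15, 0.0033 with an estimated correlation), led by EPB41L4A-AS1 at 1.68 (0.11) and C6orf48 at 1.02 (0.16). Medians of the snoRNA hosts were 0.10 in K498A (2 higher, 3 higher and 2 lower adjusted over the list alone, adjusted p = 0.124), 0.15 in DE636AA (2 higher, 3, adjusted p = 0.163) and 0.03 in A546H (0 higher, 3, adjusted p = 0.071).

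Cholesterol synthesis genes were lower than in WT in the same 4 lines. The counts were 8 of 15 in K498A (9 adjusted over the list alone, median -0.49), 8 in DE636AA (11, -0.53), 6 in R843C (8, -0.44) and 4 in A546H (7, -0.43). By camera with an estimated correlation the Benjamini-Hochberg adjusted p were 4.37e-05, 1.92e-05, 2.98e-06 and 6.46e-06. In A546H, INSIG1, which retains the sterol sensor in the endoplasmic reticulum, was at -0.78 (SE 0.13) and the squalene epoxidase SQLE at -0.53 (0.12). SQLE lost its call without each of 7 of the 12 libraries (adjusted p from 0.0238 to 0.164 over the 12, edgeR), in a fit to those libraries alone and with no filter. In GA-KH the median was -0.15 with 0 members called by edgeR over all genes and 0 adjusted over the list alone (0.00552 with an estimated correlation), and in E797R it was 0.04 (adjusted p = 0.572). Other lists were lower than in WT as well, with 0 members called by edgeR over all genes. In A546H these were histones (24 of 59 adjusted over the list alone, median -0.54, camera adjusted p = 5.1e-18, 0.0668 with an estimated correlation), ribosomal protein genes (0 of 86, -0.22, 2.68e-15, 0.136) and reference genes (0 of 12, -0.15, 0.00246, 0.0438). In R843C histones had a median of -0.40 (0 of 59 adjusted over the list alone, adjusted p = 6.18e-09, 0.219 with an estimated correlation). These 6 comparisons share the WT libraries. In the response of WT itself histones had a median of 0.12, which is part of their differences from WT.

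Counts of genes that differed from WT were 623 in K498A (276 higher, 347 lower), 860 in DE636AA (340, 520), 371 in R843C (322, 49) and 57 in A546H (49, 8). ACTA2 was at 1.71 (SE 0.22) in K498A and 2.10 (0.22) in DE636AA, and the immediate early gene EGR1 at 1.61 (0.37) and 2.26 (0.37). METTL7A was at -1.47 (0.18) and -1.56 (0.18), HTRA1 at -1.25 (0.27) and -1.26 (0.27), and the spindle checkpoint gene MAD2L1 at -1.20 (0.21) and -1.23 (0.21). ETV5 was at 1.30 (0.31) in K498A and TNFAIP3 at 1.62 (0.30) in DE636AA. EGR1 and ETV5 in K498A lost their calls without WT siNT replicate 2 and WT siUPF1 replicate 1 (adjusted p = 0.0581 and 0.0675, edgeR). In R843C, PEA15 was at 1.34 (0.13), NPIPA5, of a multi-copy family and uncertain, at 1.33 (0.27), METTL7A at -0.97 (0.18) and GALNT12 at -0.88 (0.18), and in A546H PEA15 was at 1.06 (0.13) and CLDN15 at 0.88 (0.15). HTRA1 in R843C (-1.03, 0.28), FAM13B (0.95, 0.22) and MATN2 (-0.64, 0.15) in A546H lost their calls without each of 10, 9 and all 12 of their 12 libraries, with adjusted p up to 0.176, 0.181 and 0.154 by edgeR.

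GA-KH and E797R had 0 genes called against WT by edgeR and 0 by DESeq2, with 315 and 359 genes at an unadjusted p under 0.05. With no filter on low counts 35 and 56 were called. For NMD targets the medians of the difference were 0.01 in GA-KH and 0.02 in E797R, with 0 of 15 called over all genes or adjusted over the list alone. The count in A546H was 119 by DESeq2, 153 (83 higher, 70 lower) with no filter and 9 in a fit to its own libraries, and that in DE636AA 460 in the latter. With the replicate as a block K498A had 1180, and leaving out WT siNT replicate 2 gave 355 in K498A and 509 in DE636AA. K498A had 411 without its siNT replicate 1 and 382 without its siUPF1 replicate 2. A546H had 22 without its siNT replicate 1, 24 and 36 without its siUPF1 replicates 1 and 3, 36 and 28 without WT siNT replicates 1 and 2, and 31 without WT siUPF1 replicate 1.

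With the control siRNA, WT and CLIP differed in 6 genes by edgeR, among them UPF1 (log2 difference 5.61, SE 0.20). Against WT, 5 genes were called in K498A (2 higher, 3 lower), 5 in DE636AA (2, 3), 17 in R843C (11, 6), 170 in A546H (102, 68), 17 in GA-KH (13, 4) and 9 in E797R (1, 8). In R843C the tumour suppressor RASSF1 was at 1.01 (0.11), from 15.4 to 31 CPM, and in E797R the NMD factor UPF3B was at -0.68 (0.10), from 85.6 to 53.5 CPM. In GA-KH PEA15 was at 0.61 (0.09) and GALNT13 at 0.90 (0.14), and in A546H CNTN1 was at -0.71 (0.11), ASTN1 at -0.72 (0.11), AIFM2 at 0.66 (0.11), ABHD4 at 0.79 (0.15) and SNHG11 at 0.73 (0.17). In E797R LINC01021 was at -0.88 (0.16) and DBT at -0.38 (0.07). The cystine transporter SLC7A11 was at -0.74 (0.14) in K498A and -0.82 (0.14) in DE636AA. In K498A the other called genes were PCDH19, CEBPE, CSF3R and NPAS4, and in DE636AA CTSZ, CEBPE, NPAS4 and TENM1; those of these 8 calls outside the rule were named after their values were seen. NMD factors were higher as a list in R843C (median 0.19, 1 of 9 called, 4 adjusted over the list alone, camera adjusted p = 2.06e-07 by Benjamini-Hochberg, 0.000228 with an estimated correlation) and A546H (median 0.18, 1 called, 3 adjusted over the list alone, adjusted p = 6.15e-05, 0.0096 with an estimated correlation).

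Most of these control counts rested on few libraries. The count in A546H was 355 without its siNT replicate 2, 40 and 22 without its replicates 1 and 3, and 33, 31 and 63 without WT replicates 1, 2 and 3. In R843C it was 4, 3 and 5 without its replicates 1, 2 and 3 and 3, 5 and 5 without those of WT. In DE636AA it was 11 and 1 without its replicates 1 and 3 and 3 without WT replicate 3, and in K498A 1 and 3 without its replicates 1 and 3 and 2, 1 and 2 without WT replicates 1, 2 and 3. In E797R it was 4 and 2 without its replicates 1 and 2 and 3 and 4 without WT replicates 1 and 3, and between WT and CLIP 3 without CLIP replicate 2. Fits to each comparison's own libraries called 11 genes in A546H (8 higher, 3 lower), 136 in R843C (78, 58), 44 in E797R (10, 34) and 3 in each of K498A and DE636AA. The most genes were thus called in A546H in the fit to all libraries and in R843C in these fits. DESeq2 called 469 genes in A546H (276 higher, 193 lower), 33 in R843C (24, 9), 17 in E797R (3, 14), 12 in K498A (7, 5) and 16 in DE636AA (10, 6), and with no filter on low counts the numbers were 65 (49, 16) and 113 (72, 41), and 75 (41, 34) in E797R. SMG1 (0.39, SE 0.08), AIFM2, CNTN1, ASTN1 and ITGA8 in R843C each lost their call without any 1 of the 6, and RASSF1 kept it. SLC7A11 lost its call without 5 of 6 libraries in K498A and 3 of 6 in DE636AA, with adjusted p up to 0.451 and 0.135 by edgeR. In A546H ABHD4 lost its call without 2 of 6 and SNHG11 without 4 of 6, and in E797R LINC01021 without 3 of 6 and DBT without each of the 6. PCDH19 in K498A lost it without 4 of 6 and CTSZ in DE636AA without 5 of 6.

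The NMD target score summarised the 35 genes per library. With siUPF1 it was above siNT by 0.90 on the log2 scale in CLIP (SE 0.07, from 5.03 ± 0.04 to 5.92 ± 0.12, SD, n = 3), 0.56 (0.03) in R843C, 0.34 (0.06) in DE636AA, 0.33 (0.03) in K498A and 0.21 (0.05) in A546H, each with an exact permutation p of 0.1, the smallest that 3 against 3 allows. In WT it differed by 0.02 (0.06, exact p = 1), in GA-KH by 0.01 (0.07, exact p = 0.8) and in E797R by 0.01 (0.04, exact p = 1). The difference from CLIP was -0.87 (0.09) in WT, -0.56 (0.08) in K498A, -0.56 (0.09) in DE636AA, -0.69 (0.09) in A546H, -0.89 (0.10) in GA-KH and -0.89 (0.08) in E797R, with exact permutation p adjusted by Benjamini-Hochberg of 0.0162, 0.0162, 0.0162, 0.0162, 0.026 and 0.0433. Taken within replicate numbers, the values of K498A and GA-KH, the 2 lines with all 3 correlations over 0.1, have an exact sign-flip p of 0.25, the smallest that 3 pairs allow. For R843C it was -0.34 (0.08, adjusted p = 0.065, exact permutation). Against WT the differences were 0.54 (0.06) in R843C, 0.32 (0.08) in DE636AA, 0.31 (0.07) in K498A and 0.18 (0.08) in A546H, and none passed (adjusted p = 0.13, 0.116, 0.0975 and 0.443, exact permutation), nor did GA-KH (-0.01, adjusted p = 0.937) or E797R (-0.02, adjusted p = 0.95, exact permutation). Leaving out 1 library moved 4 of these calls. E797R minus CLIP had an adjusted p of 0.065 without CLIP siNT replicate 1 or 3 and 0.0743 without E797R siNT replicate 3, and GA-KH minus CLIP 0.0542 without GA-KH siNT replicate 2 (exact permutation). R843C minus CLIP had 0.0217 without CLIP siUPF1 replicate 2 and 0.0464 without R843C siUPF1 replicate 2, and K498A minus WT 0.0371 without K498A siNT replicate 3 (exact permutation).

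**Figure D3:**
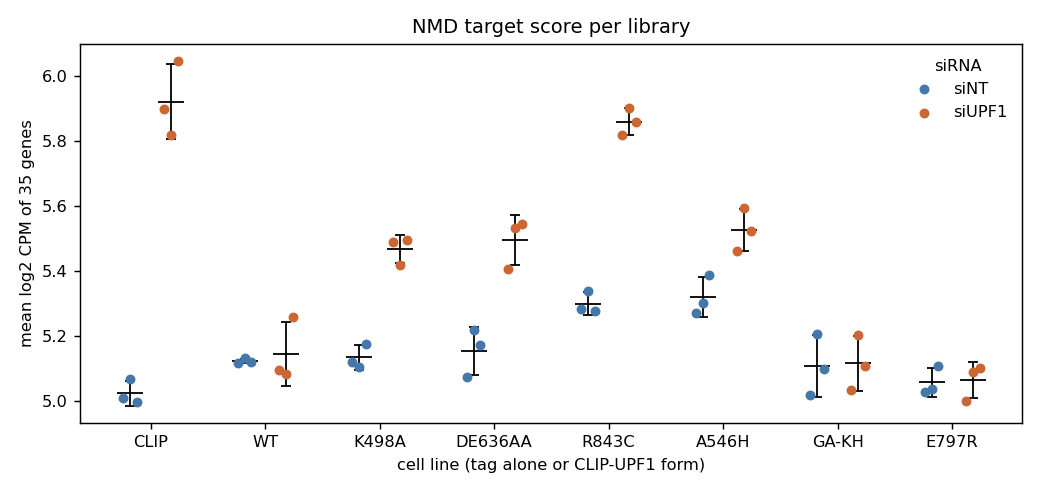
NMD target score, the mean log2 CPM of 35 genes, in each library by line and siRNA; bars give the mean and SD of 3, and the axis does not start at 0. The siUPF1 mean lies above the siNT mean by 0.90 in CLIP and 0.56 in R843C and by 0.02 or less in WT, GA-KH and E797R.

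Already with siNT the score stood above that of WT by 0.18 (SE 0.02) in R843C and 0.20 (0.04) in A546H, and the difference of CLIP from WT was -0.10 (0.02), each with an exact permutation p of 0.1, the smallest possible. All 3 libraries of R843C and of A546H (5.28 and 5.27 or above) lay above the highest of WT (5.13). The differences in K498A (0.01, exact permutation p = 0.9), DE636AA (0.03, 0.6), GA-KH (-0.02, 0.7) and E797R (-0.06, 0.1) were smaller. With siUPF1 the mean scores were 5.92 in CLIP, 5.86 in R843C, 5.53 in A546H, 5.50 in DE636AA and 5.47 in K498A. A546H had the smallest rise of these lines but not the lowest level with siUPF1.

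**Figure D4:**
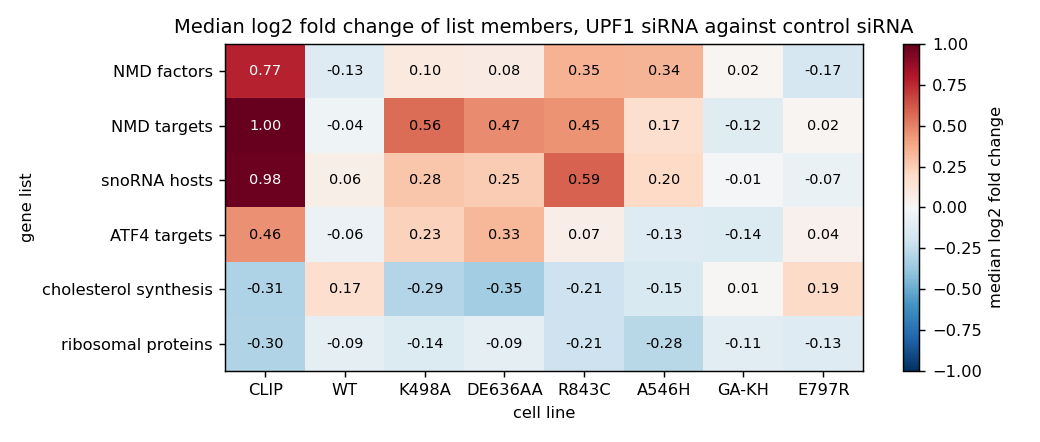
Median log2 fold change, siUPF1 against siNT, of the tested members of 6 gene lists in each line; colour gives the value printed in each cell. NMD targets have a median of 1.00 in CLIP, 0.45 to 0.56 in K498A, DE636AA and R843C, and -0.12 to 0.17 in the other lines.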

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

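The tests of the offset correction, of incomplete rescue and of the UPF1 level, the singling out of CLIP siUPF1 replicate 2 and the direct comparisons between lines with changed UPF1 were chosen after the results were seen. The responses to siUPF1 differed between lines by a test of the difference itself, an interaction in edgeR. From that of CLIP, the response differed in 2267 genes in WT, 2599 in K498A, 3430 in DE636AA, 144 in R843C, 1077 in A546H, 2734 in GA-KH and 2539 in E797R. From that of WT it differed in 623 genes in K498A, 860 in DE636AA, 371 in R843C and 57 in A546H. The change in the NMD target score differed from that in CLIP by the exact permutation test, by -0.87 in WT, -0.56 in K498A, -0.56 in DE636AA, -0.69 in A546H, -0.89 in GA-KH and -0.89 in E797R. The last of these had an adjusted p of 0.065 without CLIP siNT replicate 1 or 3 and 0.0743 without E797R siNT replicate 3, and that of GA-KH 0.0542 without GA-KH siNT replicate 2.

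Other splits of the 12 libraries of each difference, 30 per comparison with the real split included, were fitted to those libraries alone. For A546H minus CLIP 1 split, the real one, called 105 genes and the highest other 11. That share is under 0.05, but it was not adjusted over the 13 differences. Only 5 of the drawn splits kept the siUPF1 libraries in their lines, so chance is not excluded. More than 1 split was as large for WT (522 genes, highest other 700, 5 of 30 splits as large), K498A (365, 921, 3 splits), DE636AA (496, 1255, 4 splits), GA-KH (647, 1056, 5 splits) and E797R (684, 974, 4 splits) minus CLIP. The same held for K498A (516, 909, 4 splits), DE636AA (460, 2039, 6 splits), R843C (394, 1670, 6 splits) and A546H (9, 229, 4 splits) minus WT, and the splits decided none of these. R843C minus CLIP, and GA-KH and E797R minus WT, had 0 genes in these fits by edgeR and a highest other of 1, so that all 30 splits were as large. In the 9 differences where more than 1 split was as large and the real count was above 0, every other split as large had kept the siUPF1 libraries in their lines, as 5 of the drawn splits did. Such a split still holds the difference between the lines, and none of the 24 that mixed the siUPF1 libraries of the lines was as large.

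For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In the knockdown responses the real split and the highest other called 3741 and 0 genes in CLIP, 4272 and 2 in WT, 6632 and 0 in K498A, 5991 and 1 in DE636AA, 8765 and 0 in R843C, 5980 and 0 in A546H, 6199 and 0 in GA-KH and 5498 and 0 in E797R, with 1 split as large in each. With siNT the numbers were 7 and 3 for WT against CLIP, and against WT 136 and 4 in R843C, 11 and 2 in A546H, 13 and 3 in GA-KH and 44 and 8 in E797R (1 split each), 3 and 4 in K498A (2 splits) and 3 and 34 in DE636AA (3 splits).

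The response of WT was large, 5211 genes, although the NMD target score moved by 0.02. Incomplete rescue of NMD as the whole cause was taken to need a rise of at least 25% of the 0.90 in CLIP, a bar set after the values were seen. The 0.02 (SE 0.06) in WT lies below it by more than 2 SE, which argues against such a loss for the 35 genes of the score only. With each library left out the value ran from -0.03, without WT siUPF1 replicate 3, to 0.05. A smaller loss of NMD, or a loss at other genes, stays open. Genes raised at least 2-fold in CLIP moved by 0.55 in WT and 1.35 in CLIP, and which of them are NMD targets was not tested. By these genes the same bar of 25% was met, so the outcome depends on the genes used. For GC content and length the largest correlation across genes was 0.13, between the bounds of 0.1 and 0.3 set beforehand, so that test alone did not decide. Removing the trends of each library by offsets kept 98% of the genes called in WT, 4662 of 4759, which argues against such a trend as the whole cause. A candidate explanation for part of the lowered genes is an effect of the siRNA on other transcripts. Genes with the 7-mer AGAACAT in the 3′ UTR differed in median log2 fold change from those without by -0.14 in WT. It was the strongest of 14544 7-mers in all 8 lines, but all lines received the same siRNAs, so their agreement is not independent support. The 7-mer occurs in the UPF1 transcript, but in 5348 nt a 7-mer can occur by chance. The siRNA's sequence was not given in the sources used here, and 35.5% of genes lower in all 8 lines, 10.5% of those higher in all and 15.6% of the others have the site, so most of the lowered and the raised genes are not covered by it. Among 7-mers that went with higher genes, AGCAACC or the overlapping GCAACCA was strongest in all 8 lines. Its t ran from 7.5 to 9.0, against -9.4 to -12.9 for AGAACAT. What lies behind it was not tested, so an effect of either siRNA on raised genes stays open.

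The snoRNA hosts rose more in R843C than in K498A, with 8 of 20 higher in the direct comparison (median 0.42, camera adjusted p = 6.52e-12 by Benjamini-Hochberg, 0.0389 with an estimated correlation), while the NMD targets did not differ by that test (median -0.11, adjusted p = 0.627). Against DE636AA 8 hosts were higher (median 0.38, 0.0844 with an estimated correlation). A lower level of UPF1 in R843C was weighed against GA-KH, whose 4100 CPM with siUPF1 was nearest to the 3960 CPM of R843C, and whose hosts differed from WT by a median of -0.03 against 0.55 in R843C. Such a level thus went without a rise of the hosts over WT in GA-KH. As GA-KH carries another form of UPF1, this cannot separate the level from the form in R843C. That level is of the transcript, and the protein was not measured. A lower level in R843C stays open, as does a difference in what the changed forms of UPF1 do, which was not tested.

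The knockdown response of CLIP followed GC content more than that of the other lines, with a Spearman coefficient across 12501 genes of 0.44 against -0.02 to 0.19. Removing GC and length trends kept 6317 of 7788 genes (81.1%) in CLIP. The trend was largest in CLIP siUPF1 replicate 2 (0.64, against 0.06 and 0.21), and the differences from CLIP without that library were 1978 genes in WT, 2064 in K498A, 2722 in DE636AA, 183 in R843C, 820 in A546H, 1970 in GA-KH and 2122 in E797R. What set that library apart was not tested.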

How the results depend on the processing

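The gene lists and the counts of shared genes without CLIP siUPF1 replicate 2, the gene sets chosen on other replicate numbers and the offset correction were chosen after the results were seen. Of the values of named genes under the alternatives, 3433 kept their direction and their side of the threshold, 193 lost the call, 15 gained it and 0 reversed. Of the counts, 286 stayed within 1.5 times and 102 did not. Of the scores, 282 stayed, 11 moved, 5 gained and 11 lost the call, 6 of the last with the replicate block. With RLE size factors all 28 counts stayed within 1.5 times. The cause of the changes that follow was not tested. Fits to a comparison's own libraries use fewer libraries and their own estimate of the spread. They called fewer genes in CLIP (3741 against 9066) and more in R843C (8765 against 6213). Chi-square per degree of freedom between siUPF1 replicates reached 139 in CLIP and 8.33 in R843C. Whether the shared estimate understates the spread in CLIP, and so calls too many genes there, was not tested.

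DESeq2 called, with siNT against WT, 469 genes in A546H, 16 in DE636AA, 17 in E797R, 12 in K498A and 33 in R843C, 10 between WT and CLIP, 119 in A546H minus WT and 302 in R843C minus CLIP. With no filter on low counts the counts were 113 in DE636AA, 75 in E797R, 58 in GA-KH, 65 in K498A, 56 in R843C and 57 between WT and CLIP with siNT, 153 in A546H, 56 in E797R and 35 in GA-KH minus WT, and 332 in R843C minus CLIP. Fits to the comparison's own libraries gave 11 in A546H, 3 in DE636AA, 44 in E797R, 3 in K498A and 136 in R843C with siNT, 3741 in the response of CLIP, 522 in WT, 365 in K498A, 496 in DE636AA, 0 in R843C, 105 in A546H, 647 in GA-KH and 684 in E797R minus CLIP, and 9 in A546H and 460 in DE636AA minus WT.

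With the replicate number as a block the counts were 588 in A546H, 20 in DE636AA, 17 in E797R and 37 in R843C with siNT, 3612 in WT, 4136 in K498A, 353 in R843C, 2247 in A546H, 4556 in GA-KH and 3987 in E797R minus CLIP, and 1180 in K498A, 1554 in DE636AA, 643 in R843C and 159 in A546H minus WT. With siNT, in none of the 7 pairs of lines were all 3 correlations of same-numbered libraries over 0.1. The same number nonetheless gave the highest correlation for all 3 libraries between WT and each of CLIP, K498A, R843C and A546H. It did so for 2 of 3 between WT and each of DE636AA, GA-KH and E797R, so a replicate effect shared between lines is not excluded. For the score, differences within replicate numbers have the same means as without the block. The values -0.87 in WT, -0.56 in K498A, -0.56 in DE636AA, -0.69 in A546H, -0.89 in GA-KH and -0.89 in E797R minus CLIP have an exact sign-flip p of 0.25. As 3 pairs allow none smaller, the block says nothing about how stable the scores are. List tests passed in 156 cases, 39 with an estimated correlation and 112 with fry.

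The score over genes raised at least 2-fold in CLIP was above siNT with siUPF1 by 1.35 in CLIP, 0.55 in WT, 0.71 in K498A, 0.72 in DE636AA, 0.87 in R843C, 0.77 in A546H, 0.59 in GA-KH and 0.58 in E797R, and R843C minus CLIP was -0.48 and passed (adjusted p = 0.00929, exact permutation). Those genes were chosen on the CLIP libraries. With the median over members that difference was 0.96 in CLIP, 0.25 in K498A and 0.23 in DE636AA, and E797R minus CLIP was -0.92 and no longer passed (adjusted p = 0.0758, exact permutation). With RLE size factors R843C minus CLIP was -0.36 and passed (adjusted p = 0.0325, exact permutation).

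Leaving out each library in turn gave, with siNT against WT, 22 to 355 genes in A546H, 1 to 11 in DE636AA, 2 to 10 in E797R, 1 to 6 in K498A and 3 to 5 in R843C, and 3 to 5 between WT and CLIP. Minus CLIP the ranges were 1724 to 3744 in WT, 1593 to 4438 in K498A, 2344 to 5162 in DE636AA, 85 to 570 in R843C, 596 to 3300 in A546H, 1767 to 4967 in GA-KH and 1756 to 4263 in E797R, the highest in each without CLIP siUPF1 replicate 1. Minus WT they were 355 to 612 in K498A, 509 to 788 in DE636AA and 22 to 59 in A546H. Scores ran from -0.94 to -0.83 in E797R and in GA-KH minus CLIP, from -0.39 to -0.27 in R843C minus CLIP and from 0.28 to 0.37 in K498A minus WT. In the knockdown responses the ranges were within 1.5 times of the counts with all libraries.

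The 1391 genes raised in CLIP and less so in WT were chosen on the libraries that measured them, with medians of 0.78 in CLIP and 0.07 in WT. Chosen on other replicate numbers, with 1 number held out at a time, the medians were 0.65, 0.68 and 0.59 in CLIP and 0.04, 0.05 and 0.24 in WT. These folds share libraries and hold 1151, 883 and 1760 genes, so they are not replicates. With replicate 3 held out K498A also had 0.24, so WT did not stand below it there. WT siUPF1 replicate 3 had the lowest total of all libraries, 21.3 M, and an NMD target score of 5.26 against 5.10 and 5.08 in replicates 1 and 2. In the simulated counts 32.8% of 1.5-fold differences between responses were recovered, against 85.1% of 2-fold ones and 68.7% of 1.5-fold changes in the response of CLIP. Depth itself was not varied.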

Other observations

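With siNT, CEBPE and TENM1, both chosen after their values were seen, differed between lines. CEBPE was at 0.12 ± 0.045 CPM (SD, n = 3) in WT and 0.0721 ± 0.0643 in A546H, against 3.24 ± 0.195 in CLIP, 3.15 in K498A, 2.41 in DE636AA, 2.56 in R843C, 3.18 in GA-KH and 1.9 in E797R. TENM1 was at 0.722 CPM in CLIP and 0.855 in GA-KH, against 6.16 ± 0.61 in WT, 5.73 in R843C, 4.66 in K498A, 3.5 in A546H, 2.42 in DE636AA and 2.36 in E797R. The labels give 1 line for each form of UPF1, so a difference between lines that came from their derivation cannot be separated from the form they express.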
